A study of Rattus norvegicus with 6 samples.

How the data were processed

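Total RNA from the renal cortex of 6 male Sprague-Dawley rats was measured on 1-colour Agilent oligonucleotide arrays, 1 array per animal. Per the labels' protocols, 3 animals received water and 3 received nitrilotriacetic acid trisodium monohydrate (NTA) at 1000 mg per kg per day, both for 4 weeks, RNA was isolated with a column kit, and Cy3-labelled cRNA was made by linear amplification. The series calls the animals biological replicates. Per the file headers, the scanned images were processed with Agilent Feature Extraction 10.7.1.1, and the submitters' processing notes name version 10.7 of the same program. The intensity values used here are the background-corrected processed signal of each spot, deposited by the authors on a linear scale and not normalized between arrays, per the file headers. The authors also deposited a table of values in which each entry is a ratio, the processed signal divided by 1 constant per array. That constant was within 0.07% of the array's own 75th percentile, a finding from the values themselves, since the scaling is not given in the sources used here. The ratio table is on a linear scale, with column medians between 0.11 and 0.115, runs in the direction of signal, and has no centring of genes.

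Each array held 62976 spots, of which 1319 were controls and 61657 were not, 84 of the latter being spike-in probes. The scanner files carry accessions and no gene names, so a probe was named through the RefSeq gene table of assembly GRCr8, by transcript accession without its version. Of the probes, 27460 received 1 gene symbol and 34113 stayed unnamed here, among them 6746 with Ensembl transcript identifiers. The named probes covered 15284 genes. No coordinates are given, because the array annotation and the gene table rest on different genome builds. List members absent from the arrays under their symbol were matched through the table's synonyms, which named 18 of them. A further 5 members were left unmatched because their symbol now belongs to another gene, a refinement made after the data had been seen.

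The following choices were made before the data were examined. Log2 processed signal minus the array's 75th percentile over all probes that are not controls was the expression value. Control, spike-in and outlier-marked spots were left out, and saturated spots were kept. A probe was kept where it was well above background on all 3 arrays of at least 1 group, and a gene was represented by its probe with the highest mean. NTA was compared with water over all 6 arrays with limma (version 3.58.1 in R 4.3.3, lmFit and eBayes without trend), two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. In all, 11965 genes were tested. Errors given as SE come from that model, and SD is the spread between the arrays of a group.

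Also fixed in advance were 34 pathway lists and 17 cell type marker lists. Each list with at least 5 measured members was tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 51 lists, and again with an estimated correlation and with fry. Of 1019 list members, 871 were measured. The genes named in the text followed a rule fixed in advance. It takes, among the genes past the threshold whose groups do not overlap, the 10 with the largest rise and the 10 with the largest fall, or, if fewer than 10 genes pass, the 10 of smallest p in each direction. It adds, for each list described, up to 4 members that pass, or the members of highest mean signal to make 2, and 12 genes chosen whatever their values: Havcr1, Lcn2, Clu, Spp1, Mt1a, Mt2A, Cdkn1a, Hmox1, Slc30a1, Calb1, Cyp24a1 and Mki67. Mki67 was not measured under a name, and Mt1a is Mt1 in the gene table. Other genes named below were chosen after their values were seen. Some list members are counted in their lists but not reported here by name, nor drawn. Where a probe was not well above background on any array of a group, the difference is given as at least N-fold, the bright group's mean against, per array of the dim group, the higher of its own signal and the lowest signal among probes well above background.

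The fit and the list test were tested on simulated data: 20 draws of 3 against 3 arrays over 11957 genes with the measured means and spreads, 200 genes of each draw being changed. At a log2 size of 0.5, 40.3% of the changed genes were called, at 1, 83.2%, at 2, 95.5%, and at 4, 99.6%. Of 3255 calls, 192 were false. In the data 9 genes passed, so the adjusted threshold there asked for a smaller p than in the draws. The shares found in the draws therefore do not give the power of this comparison. The list of NRF2 targets, raised by 0.8 in every member, was called in 20 of 20 draws. Other lists were called 2 times in all draws, with genes simulated as independent. That size is close to this list's median in the data (0.81), so the draws do not give the sensitivity for other lists or smaller shifts.

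Slide and scan day were read from the file headers. Slide 1 held water 2 and 3, slide 2 held NTA 1 and 3, and slide 3 held water 1 and NTA 2, called the shared slide below. Slides 1 and 2 were scanned on day 1 and the shared slide on day 2, so each scan day held both groups. Alternatives covered quantile normalization, median scaling, normexp background correction with an offset of 50, the authors' ratios, 2 other background filters, outlier-marked spots kept, the mean of all probes of a gene, eBayes with trend and robust, slide as a fixed or a random block, the replicate number as a block, each array left out, and a threshold of 0.01. The normexp correction used the median spot signal in place of the planned mean signal. That change, scan day as a block, and the inclusion of unnamed features were chosen after seeing the data. The number of arrays limits the precision of every value.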

Results

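Expression was measured in the renal cortex of male Sprague-Dawley rats that were 5 weeks old at purchase. They were given water (n = 3) or NTA (n = 3), a metal-chelating aminopolycarboxylate, at 1000 mg per kg per day for 4 weeks. Between 68.4% and 73.5% of the 61657 probes on an array were well above background. The 75th percentile of processed signal was 1316.4, 1296.0 and 1301.7 on the water arrays and 1220.2, 1132.6 and 1161.3 on the NTA arrays. Saturated probes numbered 2 to 4 per array. Across genes, which are not independent replicates, pairs of arrays correlated at r of 0.9916 to 0.9941 within groups and 0.9896 to 0.9932 between groups.

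The series asks which genes differ in the renal cortex of NTA-treated rats. Targets of NRF2, the transcription factor of the antioxidant response, were higher in NTA, 25 of 28 when adjusted over the list alone, with a median log2 difference of 0.81 (camera adjusted p = 8.94e-23, and adjusted p = 0.295 with an estimated correlation). Ephx1, the microsomal epoxide hydrolase, rose 2.40-fold (log2 1.26 ± 0.10, SE, adjusted p = 0.0472). Gstp1, the pi-class glutathione transferase, rose 5.16-fold (log2 2.37 ± 0.21, adjusted p = 0.0495), and Akr7a3, an aldehyde reductase, rose 2.36-fold (log2 1.24 ± 0.11, adjusted p = 0.0495). Pir, which encodes the iron-binding nuclear protein pirin, rose 3.80-fold (log2 1.93 ± 0.15, adjusted p = 0.0472), and Aldh1l1, a folate-metabolizing dehydrogenase, rose 2.07-fold (log2 1.05 ± 0.08, adjusted p = 0.0472).

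In all, 9 of 11965 genes passed the threshold, all of them higher in NTA and 8 of them by at least 2-fold. The other 4 were Rgs11, a regulator of G protein signalling (log2 1.84 ± 0.12), Dap, a death-associated protein (log2 1.02 ± 0.08), Cnksr1, a scaffold of Ras signalling (log2 0.78 ± 0.07), and Csmd1 (log2 2.62 ± 0.24), with adjusted p between 0.0472 and 0.0495. For Csmd1, 2 of the 3 water arrays were well above background, and its difference was 1.28 under normexp. Of the 3 Rgs11 probes, the brightest, used here, had the largest difference, and the lowest stood at -0.19. With the mean of all probes Rgs11 stood at 0.57 (adjusted p = 0.173, against 0.00965 to 0.249 over its alternatives). That mean leaves little rise to the probes not used, so the Rgs11 call rests on 1 probe. For each of the 9 genes all 3 NTA arrays lay above all 3 water arrays, which also fixes their direction within the shared slide and within the other scan day. No gene was called lower by limma, while 540 were lower and 929 higher at an unadjusted p under 0.05, where chance would give 598 in all. The higher share of those genes was 63.2%, against 52.2% under quantile normalization and 50.8% under normexp. The groups did not overlap for 20.2% of genes, 1550 higher and 865 lower in NTA, where chance gives 10%. Calls of single genes changed with the processing: 0 genes passed under quantile normalization, with scan day as a block, or without any 1 array other than NTA 2 (4 genes), while normexp called 33 and eBayes with trend and robust 38. The 9 genes kept their sign in all their alternatives. Rgs11 stood at 1.83, Gstp1 at 2.32 and Pir at 1.92 under quantile normalization (adjusted p = 0.0565 for each), and at 1.84, 2.37 and 1.93 with scan day as a block (adjusted p = 0.0914, 0.107 and 0.0914), against 0.00965 to 0.249 over the alternatives of these 3 genes. With slide as a fixed block, where only the shared slide compares the groups, 5 genes passed, 1 of them among the 9.

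Among genes with lower means in NTA, none passed the test, and those of smallest p are given as values. Of these, Angptl4, Mfap1a and Retreg1 were called lower under normexp and with eBayes with trend and robust, and Tmem17, Cib2 and Asb13 with the latter. Angptl4, a secreted inhibitor of lipoprotein lipase, differed by -0.94 ± 0.13 (adjusted p = 0.0945), and Slc5a8, a sodium-coupled monocarboxylate transporter, by -1.25 ± 0.19 (adjusted p = 0.146). Lrrc52 was well above background on all 3 water arrays and on no NTA array, at least 2.65-fold lower in NTA (adjusted p = 0.0676), and Or13f5l1, an olfactory receptor gene, was at least 1.78-fold lower (adjusted p = 0.0937). The log2 differences of Mfap1a, Tmem17, Zfp37, Retreg1, Cib2 and Asb13 lay between -0.70 and -0.41. On the higher side, Slc17a1, a sodium-phosphate and urate transporter of the proximal tubule, was next after the 9 genes, at 0.72 ± 0.07 (adjusted p = 0.0513, and called in 5 alternatives).

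In the NRF2 list, of 28 measured members, 28 had a log2 difference above 0, with a median of 0.81, and 25 rose when adjusted over the list alone, against 3 over all genes tested (Ephx1, Gstp1 and Akr7a3). Nqo1, a quinone reductase, rose over the list alone by 2.71 ± 0.27 on the log2 scale, or 6.55-fold (adjusted p over all genes = 0.0648). Gstm1 rose over the list alone by 4.44 ± 0.64, or 21.8-fold (adjusted p over all genes = 0.126), with an SD of 1.11 among water arrays. Heme oxygenase 1, Hmox1, rose over the list alone by 1.11 ± 0.14 (0.0937 over all genes), and so did Srxn1, which reduces oxidized peroxiredoxins, by 1.63 ± 0.26. The members that did not pass were Cbr1 (0.09), Cbr3 (0.07) and Aldh1a1 (0.07). Nqo1, Gstm1, Srxn1, Cbr1, Cbr3 and Aldh1a1 were named after their values were seen.

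**Figure D1:**
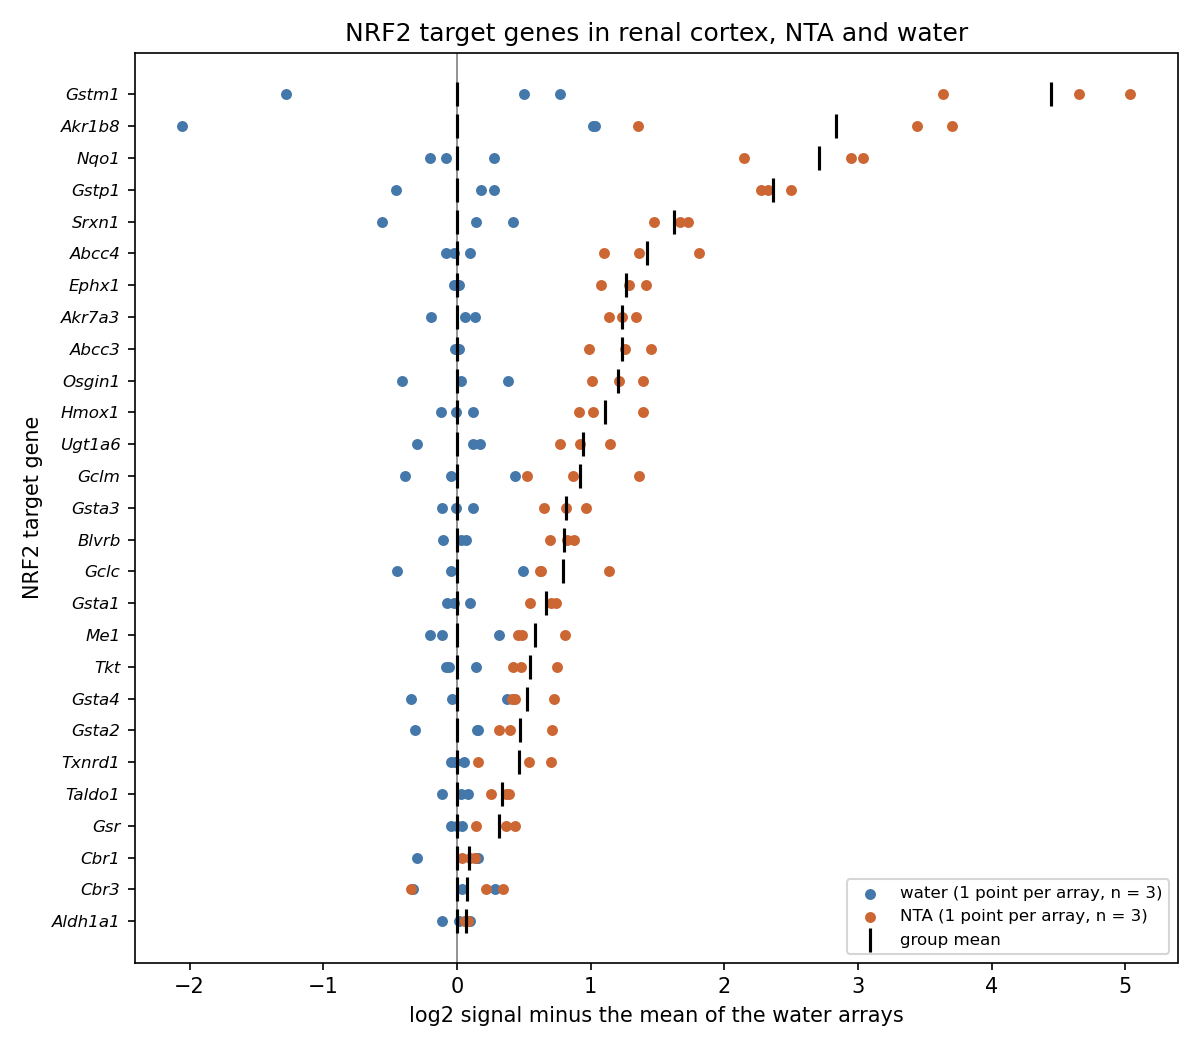
The plot gives, for each of 27 NRF2 target genes (vertical axis), the log2 signal of every array minus the mean of the water arrays (horizontal axis), with blue points for 3 water arrays, orange points for 3 NTA arrays and black bars for group means. In 24 of these genes all 3 NTA points lie to the right of all 3 water points, from Gsr (mean 0.32) to Gstm1 (mean 4.44).

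The genes of the NRF2 list moved one way by fry (adjusted p = 0.00935). The list's median was 1.07 within the shared slide and 0.67 within the other scan day. The former is also its value with slide as a fixed block, which compares 1 animal per group. The list kept its camera call in the alternatives that keep the preset correlation, and lost it with an estimated correlation (adjusted p = 0.295). Camera's p at the preset correlation rests on agreement across genes. Over the 6 arrays the list score had an exact two-sided permutation p of 0.1, the smallest possible. Mean list signal was 3.19 ± 0.03 in water and 4.28 ± 0.11 in NTA (log2 relative to the 75th percentile, SD, n = 3).

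Camera shifted 4 other lists, by smaller amounts, and each of these calls was lost with an estimated correlation (adjusted p = 0.928 with an estimated correlation). Counts of shifted lists carry little weight here, because 8 of the 9 other splits of the 6 arrays also shifted at least 5 lists, and up to 14. Transporters of drugs and organic ions were higher, with 17 of 23 members above 0 and a median of 0.21 (adjusted p = 0.00549). The efflux pumps Abcc4 (1.43 ± 0.19), which is also on the NRF2 list, and Abcc2 (1.34 ± 0.23, named after its values were seen) rose when adjusted over the list alone, and no member did over all genes. The organic anion transporters Slc22a6 (-0.09 ± 0.11) and Slc22a8 (0.05 ± 0.08), named by the rule on signal, did not pass. The list's median was 0.54 within the shared slide and 0.19 within the other scan day, and without water 1 its call was lost (adjusted p = 0.139, with 3.34e-05 to 0.139 over the alternatives that keep the preset correlation and 0.928 with an estimated correlation).

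Genes of fatty acid oxidation and targets of PPARA were lower by camera, with a median of -0.10 over 30 members, 9 of them above 0 (adjusted p = 0.000914). Adjusted over the list alone, 6 members fell and 2 rose, against 0 over all genes. Among those that fell were Angptl4 (-0.94), Vnn1 (-0.81), Cyp4a1, a fatty acid omega-hydroxylase (-0.69), Ehhadh (-0.51) and the lipid droplet protein Plin2 (-0.41). Acaa1a, a peroxisomal thiolase (0.57), and Acadm, medium-chain acyl-CoA dehydrogenase (0.31), rose. Of these, all but Angptl4 were named after their values were seen. Cyp4a2 (0.05 ± 0.07) and Cyp4a8 (0.03 ± 0.08), named by the rule on signal, did not pass. The median was -0.17 within the shared slide and -0.16 within the other scan day, and with slide as a fixed block the call was lost (adjusted p = 0.188, with 9.62e-06 to 0.188 over the alternatives that keep the preset correlation and 0.928 with an estimated correlation). Among circadian clock genes, which were not shifted as a list (median -0.02, adjusted p = 0.744), Nr1d1 stood at 0.81 ± 0.55, Dbp at 0.45 ± 0.22, Npas2 at -0.60 ± 0.24 and Bmal1 at -0.36 ± 0.16, and 0 of 15 passed over the list alone.

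Subunits of the mitochondrial respiratory chain were slightly higher, with 30 of 33 members above 0 and a median of 0.09 (adjusted p = 0.00549), yet 0 members passed over the list alone or over all genes. Atp5f1a stood at 0.13 ± 0.06 and Cox6a1 at 0.05 ± 0.07. The median was 0.17 within the shared slide and 0.06 within the other scan day, and it fell to 0.02 under quantile normalization and 0.01 under normexp, where the call was lost, as it was without NTA 2, at 0.06 (adjusted p from 0.000236 to 0.839 over the alternatives that keep the preset correlation and 0.928 with an estimated correlation). The median of all genes was 0.02.

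Podocyte markers were lower by camera, the 1 of 17 cell type lists that shifted, with 13 of 14 members below 0 and a median of -0.17 (adjusted p = 0.00648). No member passed over the list alone or over all genes, with Podxl at -0.09 ± 0.21 and Clic5 at -0.17 ± 0.11. The median was -0.15 within the shared slide and -0.13 within the other scan day. The call was lost without water 1 (-0.07) or without NTA 1 (-0.05, adjusted p = 0.204, with 0.000384 to 0.204 over the alternatives that keep the preset correlation and 0.928 with an estimated correlation).

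**Figure D2:**
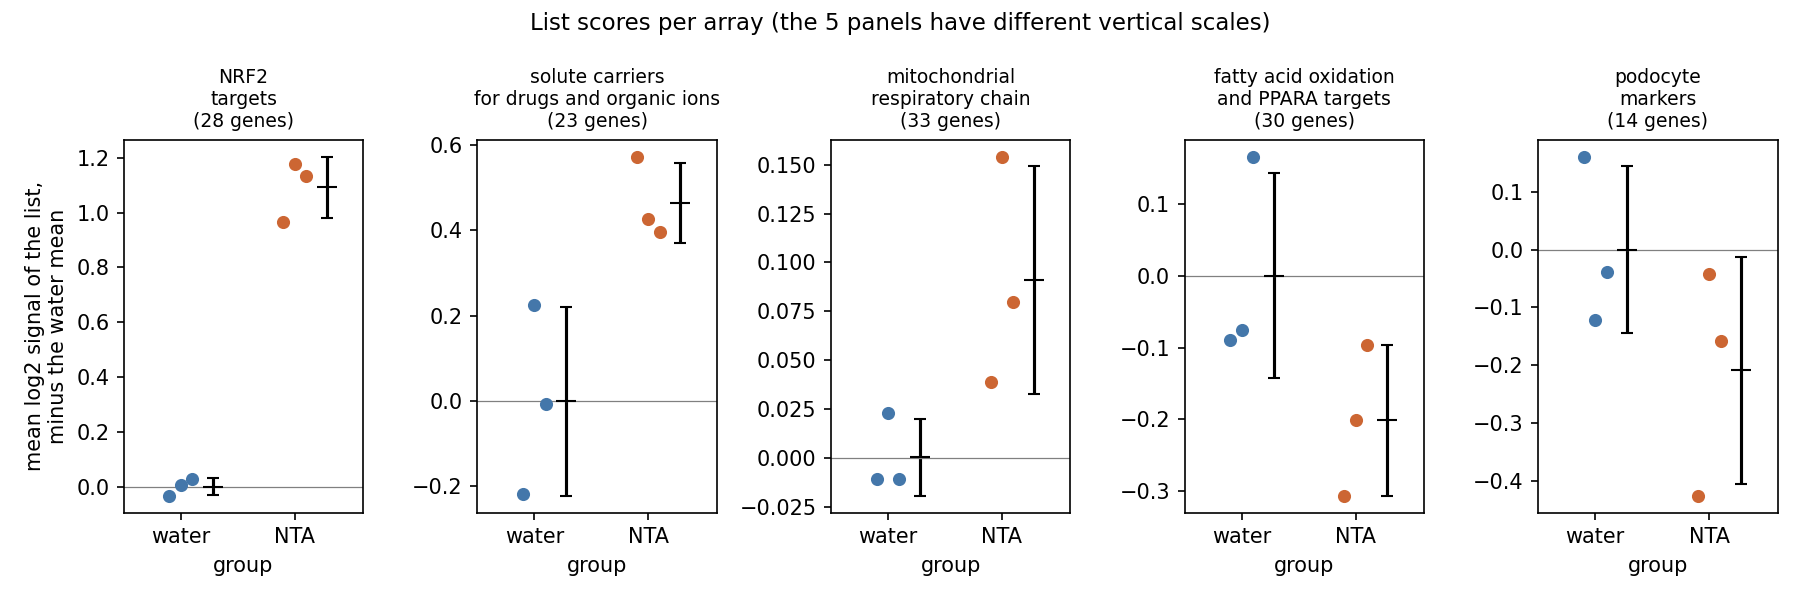
Each panel gives, for 1 list that camera shifted, the mean log2 signal of its genes per array minus the water mean (vertical axis, scaled per panel) in 3 water and 3 NTA arrays, with black bars for mean and SD. The NRF2 panel separates the groups by 1.09, while the podocyte scores of the groups overlap (difference -0.21).

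Markers of tubular injury were variable and did not pass as a list (26 members, median 0.20, 21 above 0, adjusted p = 0.116, and 0 adjusted over the list alone), though camera called them higher without NTA 2 (median 0.21). Kidney injury molecule Havcr1 stood at 0.58 ± 0.54, Lcn2 at 1.21 ± 0.87 with an SD of 1.79 among water arrays, Clu at 1.16 ± 0.41 and Spp1 at 0.45 ± 0.37, with adjusted p from 0.357 to 0.702. Within the shared slide Havcr1 differed by 1.72 and within the other scan day by 0.01. Metallothioneins and zinc exporters had a median of -0.18 over 9 members and did not pass (adjusted p = 0.063), but were called lower in 5 alternatives, among them without water 1 (median -0.17), with Mt1 at -0.47 ± 0.20, Mt2A at -0.26 ± 0.15 and Slc30a1 at 0.11 ± 0.13. Cdkn1a (0.16 ± 0.09), a p53 target, Calb1 (0.13 ± 0.17), a distal tubule calcium buffer, and Cyp24a1 (-1.20 ± 0.46), which degrades vitamin D, did not pass. Of the 3 Cdkn1a probes only the brightest, used here, was above 0, and the lowest stood at -0.41. The 2 probes of Asb13, of Cyp4a2 and of Slc22a8 also differed in sign. Cell cycle genes were not shifted (26 members, median 0.02, adjusted p = 0.878) except without NTA 1 (median 0.22) and with slide as a fixed block (0.35), with Cdk1 at -0.03 ± 0.19.

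The iron handling list was not shifted as a whole (24 members, median 0.00, adjusted p = 0.493), yet 3 members rose when adjusted over the list alone, against 0 over all genes. They were the transferrin receptor Tfrc (1.08 ± 0.14), the ferric reductase Cybrd1 (1.28 ± 0.17) and the iron importer Slc11a2 (0.43 ± 0.08), named after their values were seen. The ferritin genes Ftl1 (0.19 ± 0.07) and Fth1 (0.17 ± 0.08) did not pass.

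The 46 lists that were not shifted had medians from -0.20 to 0.53. The highest belonged to the proximal tubule S3 segment (13 members, adjusted p = 0.19, and called with the mean of all probes at 0.56), in which Abcc4 rose and Slc5a8 fell over the list alone. Abcc4 and Gsta4 (0.53 ± 0.20), whose value is the list's median, are also on the NRF2 list, so the 2 lists are not independent. Over their lists alone, the transcription factor genes Fosl2 (0.58) and Maff (0.95) rose among immediate early genes and the small heat shock protein Cryab (1.26) rose among papilla genes. General proximal tubule genes had a median of 0.01 (24 members, adjusted p = 0.951), and those of the thick ascending limb 0.13, the endothelium -0.08 and macrophages 0.11, none of them shifted. Leaving out 1 array changed this for the endothelium (-0.13 without water 2) and for macrophages (0.26 without NTA 2), and normexp for the endothelium (-0.12). Complement and antigen presentation genes, with overall medians of 0.10 and 0.08, differed in sign between the shared slide and the other scan day. Within the shared slide, water 1 against NTA 2, the medians were -0.38 and -0.40, and within the other scan day 0.37 and 0.26. Mean list signal was lowest in NTA 2. For complement it was 0.36, against 0.96 in NTA 1, 0.93 in NTA 3 and 0.53 to 0.78 in water. For antigen presentation it was 2.06, against 2.42, 2.70 and 2.19 to 2.46. Without NTA 2 both lists were called higher, at 0.29 and 0.24. With slide as a fixed block, which compares only water 1 with NTA 2, both medians were below 0.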

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

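The tests of scan day for NRF2 targets and by the size of differences within days, of paralogs, of array scaling, of the time of collection and of glomerular sampling were chosen after the results were seen. The probes that received no gene name were left out of the main comparison above. Whether some of them target genes already tested there was not checked. Of 19138 such features tested apart with limma, 12 changed, 11 higher and 1 lower in NTA, and 1879 had an unadjusted p under 0.05. The feature TC611761 was well above background on all 3 NTA arrays and on no water array, at least 6.71-fold higher (adjusted p = 0.00297), and FQ214633 was 5.67-fold lower (log2 -2.50 ± 0.14, adjusted p = 0.0127). Both were picked after their values were seen.

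The rise of NRF2 targets and of the 9 called genes is the clearest pattern. For the NRF2 list, whose genes were fixed in advance, a rise seen on 1 scan day alone is argued against. The lower of its medians within days was 0.67. That value, from day 1, sets water arrays on slide 1 against NTA arrays on slide 2, so it may hold a slide difference. Only the shared slide, with 1 array per group, compares the groups within a slide, at a median of 1.07. For the 9 genes a shift between days cancels, because each day held both groups in equal numbers, but whether their differences rest on 1 day stays open: 100% kept their direction on both days and the lowest difference within a day was 6 SEs (Csmd1), which the choice of genes on the same arrays nearly fixes. With scan day as a block 0 of the 9 were called, at the same log2 differences and with SEs larger for 5 and smaller for 4 (Aldh1l1 1.05 ± 0.08 before and 1.05 ± 0.09 after, Rgs11 1.84 ± 0.12 and 1.84 ± 0.11), because residual degrees of freedom fell from 4 to 3: the 9 passed with the block's SEs alone and 0 passed with its degrees of freedom alone. Signal shared between paralogs is argued against as the whole source. Left out were glutathione transferases, glucuronosyltransferases, aldo-keto and carbonyl reductases, aldehyde dehydrogenases and ABC transporters. The 14 NRF2 members outside these families, which still hold other reductases such as Nqo1, differed by 0.956 in mean signal, with a pooled SD of 0.107. Of the 10 splits of the 6 arrays, too few for a share under 0.05, 1 gave as many called genes, the real one, with 9 against 2 in the highest other split, and its NRF2 median of 0.81 compares with 0.44 at most in the others.

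The lower PPARA targets were not removed by scaling, since the median nearest to 0 over the other scalings was -0.10 and each of these scalings kept the call at the preset correlation, which is lost with an estimated correlation (adjusted p = 0.928). A different time of collection may bear on them, as many of these genes follow feeding and the clock, so clock genes of opposite phase were set against each other (Nr1d1, Nr1d2, Dbp, Tef, Per3 and Usp2 minus Bmal1, Npas2, Clock, Cry1 and Nfil3). That contrast was 0.795 higher in NTA, with a pooled SD of 0.473 and overlapping arrays (exact two-sided permutation p = 0.2, smallest possible 0.1), at 0.46 within the shared slide and 0.96 within the other scan day. Collection time and an effect of NTA on these genes cannot be told apart, because the labels give no time and 3 arrays per group leave the contrast undecided. For the count of shifted lists, 9 of the 10 splits, the real one included, gave at least 5, with 14 in the highest other split, and 10 splits are too few for a share under 0.05.

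Whether the lower podocyte markers come from an uneven share of glomeruli in the cortex pieces is not settled. The test asked only whether the list's scores overlap between groups and spread as widely as the group difference. Any spread of that size between arrays would meet it, so it cannot single out glomeruli. The mean signal of the list differed by -0.209, with a pooled SD of 0.172, and NTA 2 (0.94) lay above water 2 (0.861). An effect of NTA on podocytes also stays open and was not tested apart from the share of glomeruli.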

How the results depend on the processing

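The normexp correction on median signal, scan day as a block and the unnamed features were chosen after the data were seen. Against 9 genes changed (9 higher, 0 lower, 8 at least 2-fold), quantile normalization, no background filter, scan day as a block and a threshold of 0.01 gave 0, with limma's unadjusted counts at 1415, 1364, 1513 and 1469. Median scaling gave 4 (4 higher, 4 at least 2-fold), normexp 33 (28 higher, 5 lower, 15 at least 2-fold), eBayes with trend and robust 38 (32 higher, 6 lower, 18 at least 2-fold) and slide as a fixed block 5 (4 higher, 1 lower, 5 at least 2-fold). With unnamed features there were 16 (15 higher, 1 lower, 16 at least 2-fold). The authors' ratios, outlier-marked spots kept and the all-array filter each gave 9, the mean of all probes 12 and slide as a random block 10. Leaving out 1 array gave 0 to 4 genes changed, 0 to 4 higher and 0 to 4 at least 2-fold, with 1069 to 1352 at an unadjusted p under 0.05. The replicate number shared by the labels was not used to pair the animals in the main comparison, as the series states no pairing. Same-numbered arrays deviated together at r of 0.073, -0.092 and 0.036, and not every array correlated best with its own number. Because same-numbered arrays lay on different slides, these values cannot exclude a pairing. The replicate block gave 0 genes changed, 0 higher and 0 at least 2-fold (1252 unadjusted). Against 5 lists shifted, slide as a fixed block gave 13, an estimated correlation 0 and fry 1, and leaving out 1 array gave 4 to 8. With slide as a fixed block, where only water 1 and NTA 2 are compared, the medians of 14 of 51 lists changed sign, 12 to below 0 and 2 to above, and 2 of the 14 passed the threshold, complement at -0.38 and antigen presentation at -0.403. The NRF2 list kept its direction and its call in 19 of 19 alternatives that keep the preset correlation, with medians from 0.70 to 1.07, and lost its call with an estimated one (adjusted p = 0.295), and its median within the shared slide ranged from 0.96 to 1.13. For the other changes the cause was not tested. Among named genes, no called value changed sign. Uncalled values changed sign 69 times in alternatives that keep all arrays and 52 times with 1 array left out, calls were lost 51 and 51 times, and calls were gained 15 and 0 times. For lists, calls were gained 15 and 11 times and lost 12 and 4 times. Dim probes limit what could be seen, as 68.4% to 73.5% of probes were well above background.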

Other observations

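The tests in this part were all chosen after the results were seen. Conjugating enzymes outside the NRF2 list were also higher in NTA. Over 26 genes with Gst, Mgst or Ugt symbols (glutathione transferases and UDP-glycosyltransferases) that the list does not hold, 24 had log2 differences above 0 and the median was 0.67. The set was taken by symbol and so holds Ugt8 (-0.02), which is not a glucuronosyltransferase. Camera shifted this set against other genes (adjusted p = 8.44e-13 over 4 sets, and adjusted p = 0.0231 with an estimated correlation). The 4 sets overlap: they were this one, its Gst and Mgst part, its Ugt part and the sulfotransferases. The NRF2 list was instead adjusted over all lists fixed in advance. Its adjusted p with an estimated correlation therefore cannot be compared with that of the 26 genes. Adjusted over the 26 genes alone, a set chosen after the results were seen, 17 rose and 0 fell. Over all genes 0 passed (lowest adjusted p 0.0676, Mgst1). Among the glucuronosyltransferases, which attach glucuronic acid to drugs, steroids and bilirubin, Ugt2b15, Ugt2b37 and Ugt2b35 stood at 1.88, 1.88 and 1.84, and Ugt1a2 at 0.91. Among the transferases, Gstp3 stood at 1.24, Gstm4 at 1.21 and the membrane-bound Mgst1 at 0.74. The set's median was 0.42 within the shared slide and 0.69 within the other scan day. These families hold close paralogs, so 1 strongly raised member could add signal to the probes of its neighbours, and the count of raised genes may be too high. Sulfotransferases, another conjugating family, were not shifted (7 genes, median 0.16, adjusted p = 0.887), and Sult1c2 stood at -0.88 and Sult2b1 at 0.42.

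The rise of Tfrc, Cybrd1 and Slc11a2 is a candidate sign of an altered cellular iron supply under a chelator, as a hypothesis only. A hypoxia response, which raises some of the same genes, was weighed against it. Of the hypoxia response members, 95% had a log2 difference below that of Slc11a2, the lowest of the 3. Because the 3 genes were picked for their rise, that share was nearly fixed and decides nothing. The hypoxia list, fixed in advance, was not shifted by camera (20 members, median 0.05, adjusted p = 0.852). An unshifted list does not exclude hypoxia as a source of the 3 rises. Iron itself was not analysed here, so the hypothesis stays open.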
